A study of Homo sapiens with 14 samples.

How the data were processed

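Total RNA of MiaPaCa2 cells was labelled with a whole-transcript cDNA kit and hybridized to 14 Affymetrix whole-transcript arrays, as the labels state. Cells were transfected with INTERFERin and a scrambled control siRNA or an siRNA against NUPR1, RELA or RELB. The arrays form a set of 6 (siCtrl, siRelA and siRelB, each in EBSS and in mock at 9 h) and a set of 8 (siCtrl and siNupr1, each at 0 h and after 3, 6 and 9 h in EBSS). The title of the siNupr1 array at 9 h names a different siRNA from its source and description, which both give siNupr1. It was used as siNupr1. The 0 h arrays' titles name DMEM, a culture medium, while their source field names EBSS for 0 h; they were used as unstarved, and the medium is in doubt.

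The deposited values are log2 values that the authors made by robust multi-array average (RMA), which corrects background, quantile normalizes and summarizes the probes of each transcript cluster. The RMA version and the annotation are not given in the sources used here. The authors' notes also name limma, without a version or a design. The file held 28869 transcript clusters, with 0 missing values. Of these, the array annotation listed 21062, namely 19310 with 1 gene symbol and 1752 with several, and 7807 were not listed. Clusters with 1 symbol were matched to current symbols by Entrez identifier (19279 of them), which gave 18377 genes. Where a gene had several clusters (685 genes, among them IER3 with 3 clusters) the one with the highest mean over all arrays was used. The 40% of genes with the lowest mean were left out, a level of 5.805 on the log2 scale, and 11026 genes were tested. No genome build is named for these clusters, so no coordinates are printed. A GRCh38.p14 gene table served only for symbols, gene types, the genomic span of genes and the nesting of small RNA genes in host genes.

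The values were analysed with R 4.3.3, limma 3.58.1 and data.table (version 1.17.8). No arrays were left out and the deposited scaling was kept. A joint linear model of set, siRNA and condition with 9 columns was fitted (lmFit, then eBayes with an intensity trend), which left 5 residual degrees of freedom and 19.6 in total after moderation. Its residuals hold noise and any dependence of an siRNA's difference on the condition, since every combination was measured on 1 array. It gave EBSS against mock at 9 h (3 pairs), EBSS at 3, 6 and 9 h against 0 h (2 pairs each), siNupr1 against siCtrl (4 pairs), siRelA and siRelB against siCtrl and siRelB against siRelA (2 pairs each). A slope of the siNupr1 difference on hours, and a difference of the siRelA and siRelB differences between EBSS and mock, were added in turn. In the latter fit the spread came from the Nupr1 set alone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison. Differences of single pairs of arrays are given as values without a test.

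Gene lists, 29 in number, were written before the data were examined, as were the comparisons, tests, filters, the rule for named genes and the first alternatives. They are canonical NF-kB targets, alternative NF-kB pathway components, the ATF4 and amino acid response, aminoacyl-tRNA synthetases, ER chaperones, autophagy and lysosome, FOXO targets, immediate early genes, cholesterol biosynthesis, G2/M, DNA replication and G1/S, ribosome biogenesis, ribosomal proteins, p53 targets, anti-apoptotic and pro-apoptotic regulators, interferon-stimulated genes, glycolysis, hypoxia targets, NRF2 targets, heat shock proteins, oxidative phosphorylation, metallothioneins, histones, and markers of fibroblasts, leukocytes, endothelium, acinar cells and epithelium. Lists with at least 3 tested members were tested with camera (correlation 0.01), adjusted over the lists of a comparison, and members were also counted with p adjusted over the list alone. As alternatives the correlation was estimated for each list, and fry was used.

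Named genes are NUPR1, RELA, RELB and IER3 in every comparison, genes among the 10 largest rises and falls past the threshold with the same sign in every pair, up to 4 members of each list with the largest change, and every canonical NF-kB target past the threshold. Where no gene passed, those with the smallest p are named and said not to pass. The rule called IER3 a silenced gene, as the protocols do, although no array here carried its siRNA. Overlaps of calls were tested with Fisher's exact test, beside 100 simulated draws of unchanged groups on shared siCtrl arrays for siRelA and siRelB. The difference of the starvation response between the sets was a contrast of the same fit, chosen after the data were seen.

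The fits were tested on simulated data with the same design and spread. Of changes of 1.5-fold, 98.5% were recovered for EBSS against mock, 86.6%, 77.6% and 80.6% at 3, 6 and 9 h, 100% for siNupr1, 83.6% for siRelA and 85.1% for siRelB. There were 4 to 12 false calls per comparison and 0 with the wrong sign. The simulated noise was independent between genes and arrays, without array-wide shifts or siRNA differences that depend on the condition. These counts therefore do not give the rate of false calls on the real arrays.

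Alternatives set beforehand were no filter or a stricter one, quantile normalization, eBayes without trend or robust, array weights, the mean of a gene's clusters, the spread of the own set alone, leaving out each array, the 3 starved pairs and no time term for siNupr1, the list tests above, and unadjusted p for the overlaps. Leaving out small non-coding RNA genes, and removing a loess trend on gene span from each array, were added after the data were seen. Clusters without a single symbol were left out of the comparisons. Probe-level files and siRNA sequences were not used here.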

Results

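Gene expression was measured on 14 Affymetrix whole-transcript arrays, each hybridized with RNA of MiaPaCa2, a human pancreatic cancer cell line. The cells had been transfected with a small interfering RNA (siRNA, which silences the gene it is designed against) for NUPR1, RELA or RELB, or with a scrambled control siRNA (siCtrl). NUPR1 encodes a small stress-induced chromatin protein, and RELA and RELB encode DNA-binding subunits of the transcription factor NF-kB. Starved cells were held in Earle's balanced salt solution (EBSS), which lacks amino acids and growth factors; the labels say that it lacks glucose too, although the usual formula contains it. The Nupr1 set had 8 arrays, siCtrl and siNupr1 at 0 h and after 3, 6 and 9 h in EBSS. The siNupr1 array at 9 h has a title that names a different siRNA from its source and description. It was used as siNupr1, and the siNupr1 differences at 9 h carry that doubt. The titles of the 0 h arrays name a culture medium and their source field names EBSS for 0 h, so they were taken as unstarved, which the starvation differences at 3, 6 and 9 h rest on. The NF-kB set had 6 arrays, siCtrl, siRelA and siRelB at 9 h in EBSS or in a mock medium whose composition the labels do not give. Every combination of siRNA, medium and time was measured on 1 array, so there were no replicates, and the labels do not say whether arrays came from separate cultures. The array medians lay between 5.67 and 5.84 on the log2 scale, and the small number of arrays limits the precision. Differences are log2 differences ± SE from a limma fit, and n counts the pairs of arrays that carry them. The siCtrl arrays in EBSS at 9 h, 1 in each set, correlated at r = 0.905 across genes, which are not independent replicates, and 9.26% of their genes were at least 2-fold apart. Differences between conditions were therefore taken within a set. The first principal component, with 42.8% of the variance, parted the sets.

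NUPR1, RELA and RELB were each lower where their own siRNA was used. NUPR1 was lower with siNupr1 by a log2 difference of -0.87 ± 0.10 (n = 4 pairs, adjusted p = 1.95e-05), with -0.69 at 0 h, -0.92 at 3 h, -1.21 at 6 h and -0.65 at 9 h. On the siNupr1 0 h array it lay at 5.59, a dim signal under the filter's level of 5.805. RELA was lower with siRelA by -2.49 ± 0.13 (n = 2 pairs, adjusted p = 2.96e-10), with -2.63 in EBSS and -2.36 in mock. RELB was lower with siRelB by -1.32 ± 0.17 (n = 2 pairs, adjusted p = 3.62e-05), with -1.68 in EBSS and -0.95 in mock. RELB was also lower with siNupr1, by -0.67 ± 0.12 (n = 4 pairs, adjusted p = 0.000945), with -1.20 at 9 h and between -0.54 and -0.44 at the earlier times. The 9 h values of NUPR1 and RELB rest on the siNupr1 array whose title names a different siRNA. NUPR1 was lower with siRelB by -0.43 ± 0.14 (adjusted p = 0.0442), a call that was lost in 8 of the 14 fits that left out 1 array and without the filter on dim genes, with adjusted p of up to 0.318. In a fit of the Nupr1 set alone without the time term the siNupr1 calls of NUPR1 and RELB were lost (adjusted p = 0.148 and 0.355). That fit gives up the pairing by time and counts differences between times as noise, so lost calls are likely in it. RELA differed by -0.04 ± 0.09 with siNupr1 (adjusted p = 0.841) and by 0.02 ± 0.13 with siRelB (adjusted p = 0.958), and RELB by -0.36 ± 0.17 with siRelA (adjusted p = 0.15). IER3, a stress-inducible gene with a part in cell survival, is named in the protocols as a further siRNA target, and none of the 14 arrays carried that siRNA.

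**Figure D1:**
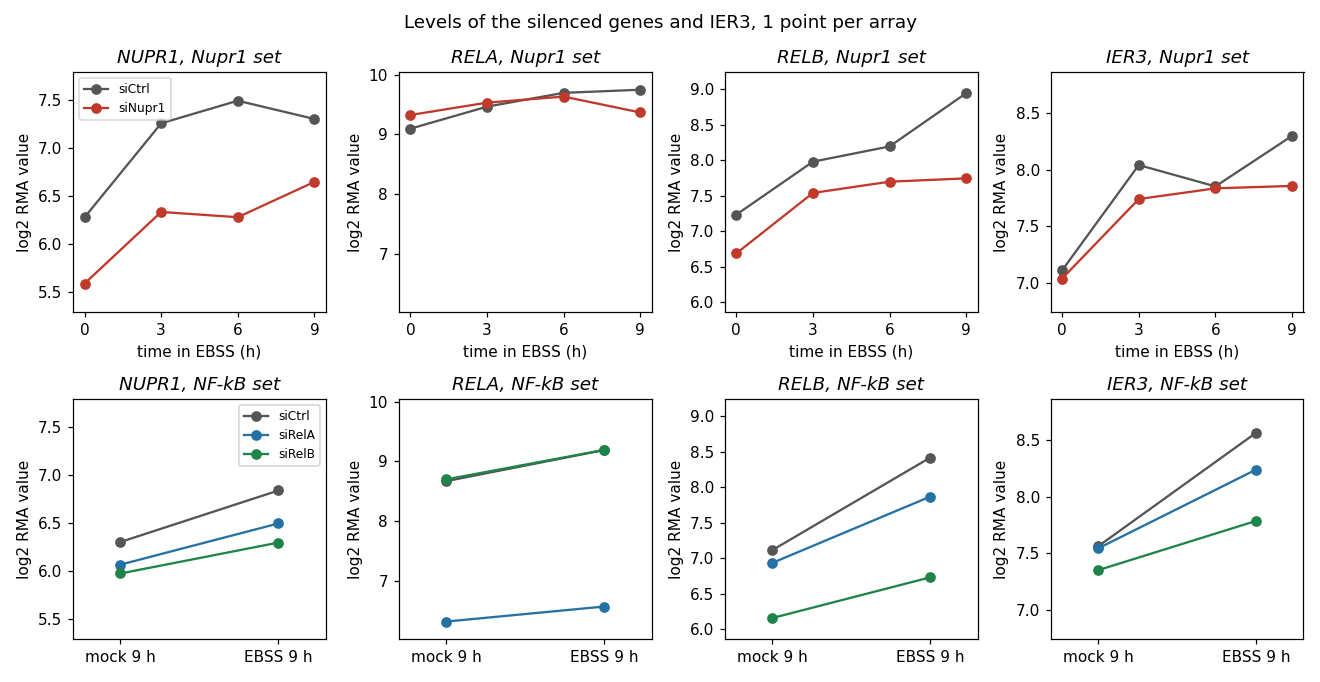
Log2 RMA levels of NUPR1, RELA, RELB and IER3, 1 point per array, against hours in EBSS for the Nupr1 set (top; 0 h was taken as unstarved) and against medium for the NF-kB set (bottom). NUPR1 lay lower with siNupr1 than with siCtrl at all 4 times, and RELA with siRelA and RELB with siRelB lay lowest in both media.

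The Nupr1 set shows how these cells changed over hours in EBSS in siCtrl and siNupr1 pairs. After 9 h, SLC7A11, the cystine transporter, was higher by 3.39 ± 0.17 (n = 2 pairs, adjusted p = 8.88e-11). The stress transcription factor gene DDIT3 was higher by 2.78 ± 0.19, TRIB3 by 2.72 ± 0.17 and SESN2, which restrains the growth regulator mTORC1, by 2.15 ± 0.22. Among the 10 largest falls at 9 h were ID3 (-2.80 ± 0.12) and ID2 (-2.52 ± 0.22), which encode inhibitors of helix-loop-helix transcription factors. SKP2, a ubiquitin ligase subunit that promotes entry into S phase, fell by 2.34 ± 0.14 and the replication origin gene ORC1 fell by 1.97 ± 0.13. Of 11026 genes tested, 361 rose and 1000 fell at 3 h, 844 rose and 1736 fell at 6 h, and 1013 rose and 1662 fell at 9 h. Of these, 32, 47 and 104 rose and 39, 106 and 100 fell at least 2-fold. NUPR1 itself was higher by 0.86 ± 0.14, 0.95 ± 0.14 and 1.04 ± 0.14 at 3, 6 and 9 h, RELB by 0.80 ± 0.17, 0.98 ± 0.17 and 1.38 ± 0.17, and IER3 by 0.82 ± 0.14, 0.77 ± 0.14 and 1.0 ± 0.14, all past the threshold. These are means over siCtrl and siNupr1 cells, and NUPR1 was silenced in the latter. The RELB call at 3 h was lost without the siCtrl 0 h or the siNupr1 3 h array (adjusted p of up to 0.133). RELA was higher by 0.46 ± 0.13 at 6 h (adjusted p = 0.0172; up to 0.297 with 1 array left out), and its differences at 3 and 9 h did not pass (0.29 ± 0.13 and 0.35 ± 0.13). The counts moved with single arrays: at 3 h 499, 474 and 356 genes were called without the siCtrl 0 h, siCtrl 3 h and siNupr1 3 h arrays, at 6 h 1230 and 823 without the siCtrl 0 h and 6 h arrays, and at 9 h 1639 without the siCtrl 0 h array. The balance of directions moved too. At 6 h 464 rose and 1272 fell without the siNupr1 6 h array. At 9 h 628 rose and 1506 fell without the siCtrl 9 h array, against 1081 and 1083 without the siNupr1 9 h array. Array weights gave 2173 genes at 3 h and 1517 at 9 h. After quantile normalization the share of called genes that rose was 42.7% at 3 h and 44.4% at 6 h, against 26.5% and 32.7% on the deposited values, and 45.5% at 9 h against 37.9%.

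By gene list, the ATF4 and amino acid response had 29 measured members, of which 23, 25 and 27 rose at 3, 6 and 9 h and 0 fell (26, 26 and 28 adjusted over the list alone). Camera gave adjusted p of 8.17e-29, 2.63e-23 and 1.43e-31, and with an estimated correlation adjusted p = 0.113, 0.132 and 0.11. Of 27 members of DNA replication and G1/S, 22, 24 and 25 fell (24, 25 and 25 adjusted over the list alone), among them GINS2 (-1.72 ± 0.14 at 9 h), MCM10 (-1.60 ± 0.14) and MCM3 (-1.43 ± 0.12). Camera's largest adjusted p over the 3 times was 6.43e-21, and with an estimated correlation adjusted p = 0.113, 0.132 and 0.11. Of 26 genes of the G2/M cell cycle, 15, 24 and 14 fell (22, 24 and 16 adjusted over the list alone), with KIF20A at -1.07 ± 0.13 and CCNA2 at -0.86 ± 0.12 after 9 h. By camera the adjusted p was at most 2.09e-05, and with an estimated correlation adjusted p = 0.169, 0.155 and 0.274. Of 14 heat shock proteins, 10, 11 and 10 fell (12, 11 and 12 adjusted over the list alone, and 1 rose at 3 h). DNAJA1 was at -1.25 ± 0.12, HSPA4L at -0.99 ± 0.16 and BAG3 at -0.89 ± 0.12 after 9 h. The camera adjusted p was at most 2.89e-06, and with an estimated correlation adjusted p = 0.113, 0.132 and 0.11.

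Of 28 immediate early and serum response genes, 18 rose at each of the 3 times and 0 fell (20, 24 and 22 rose adjusted over the list alone, and 1 fell at 6 h). KLF4 was at 1.66 ± 0.16, EGR1 at 1.33 ± 0.20 and CCN1 at 1.06 ± 0.20 after 9 h. Over the 3 times the camera adjusted p was at most 1.12e-12, and with an estimated correlation adjusted p = 0.134, 0.22 and 0.167. Of 9 metallothionein and zinc response genes, 6, 9 and 7 rose (6, 9 and 8 adjusted over the list alone), with MT1M at 1.44 ± 0.13 and the zinc exporter SLC30A1 at 1.19 ± 0.12 after 9 h. With the span trend removed 4 rose at 3 h and the median went from 0.30 to 0.19, and camera's call was kept. Metallothionein genes are near-identical copies, so it is uncertain which of them a cluster measured. Camera gave an adjusted p of at most 1.46e-07, and with an estimated correlation adjusted p = 0.113, 0.0614 and 0.107. Of 33 autophagy and lysosome genes, 5, 11 and 12 rose and 0, 2 and 1 fell (6, 12 and 12 against 0, 2 and 1 adjusted over the list alone). MAP1LC3B, which coats autophagosome membranes, was at 1.66 ± 0.15, WIPI1 at 1.19 ± 0.14 and the autophagy receptor SQSTM1 at 1.11 ± 0.10 after 9 h. The camera adjusted p was at most 0.00409, and with an estimated correlation adjusted p = 0.504, 0.359 and 0.261. Of 18 FOXO targets, 8, 11 and 10 rose and 2, 1 and 1 fell (9, 12 and 10 against 2, 1 and 1 adjusted over the list alone), with YPEL2 at 1.59 ± 0.17 after 9 h. The camera adjusted p was at most 2.29e-05, and with an estimated correlation adjusted p = 0.223, 0.22 and 0.167.

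After 9 h, 11 of 19 cytosolic aminoacyl-tRNA synthetases rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 5.27e-06; adjusted p = 0.11 with an estimated correlation), with CARS1 at 1.33 ± 0.15. Of 19 p53 targets 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00102; adjusted p = 0.167 with an estimated correlation). They included the death receptor gene TNFRSF10B (1.54 ± 0.12) and GDF15 (1.45 ± 0.14). Of 14 hypoxia targets 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00527; adjusted p = 0.167 with an estimated correlation), with VEGFA at 1.66 ± 0.15. Of 11 anti-apoptotic regulators 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.00984; adjusted p = 0.331 with an estimated correlation), with BCL2L1 at 0.73 ± 0.12 beside IER3. Of 30 canonical NF-kB targets with a cluster of their own 17 passed the filter on dim genes. TNFAIP3, ICAM1 and IL6 were among those left out. Of the 17 canonical NF-kB targets tested 5 rose and 0 fell, also when adjusted over the list alone: LIF (1.79 ± 0.14), IER3, CXCL2 (0.99 ± 0.15), NFKB2 (0.72 ± 0.13) and PLAU (0.55 ± 0.10). Its camera adjusted p was 0.00841, and adjusted p = 0.37 with an estimated correlation. Of 21 genes of oxidative phosphorylation 5 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.486 with an estimated correlation), with NDUFB3 at -1.04 ± 0.17. For the other lists camera made no call at 9 h. Of 16 NRF2 targets 4 rose and 1 fell, of 19 glycolysis genes 4 rose and 0 fell (SLC2A3 at 1.28 ± 0.14), and of 19 interferon-stimulated genes 1 rose and 4 fell. Of 21 pro-apoptotic regulators 4 rose and 2 fell (CASP2 at -1.11 ± 0.12), and of 8 alternative NF-kB components 3 rose and 1 fell; the counts of these 5 lists were the same adjusted over the list alone. Of 24 ribosome biogenesis genes 3 rose and 4 fell (3 and 5 adjusted over the list alone), of 17 cholesterol genes 1 rose and 3 fell (2 and 6 adjusted over the list alone), and of 19 ribosomal proteins 0 changed by limma in either count. Of 20 ER chaperones 6 rose and 8 fell (7 and 9 adjusted over the list alone). The median and the mean of the list had opposite signs for ER chaperones (-0.11 and 0.06), glycolysis (-0.04 and 0.10) and pro-apoptotic regulators (-0.02 and 0.08). Of 18 replication-dependent histones 1 rose and 2 fell at 9 h in both counts, and 8 fell at 6 h (10 adjusted over the list alone; camera adjusted p = 0.000947; adjusted p = 0.503 with an estimated correlation).

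At 3 and 6 h camera called further lists. Of 24 ribosome biogenesis genes 8 fell and 0 rose at 3 h (9 and 1 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.269 with an estimated correlation). At 6 h 9 fell and 2 rose (11 and 3 adjusted over the list alone), without a call by camera (adjusted p = 0.057). The 17 canonical NF-kB targets had 4 that rose and 0 that fell at both times (7 and 1 at 3 h and 4 and 0 at 6 h adjusted over the list alone): LIF (1.53 ± 0.14 and 1.58 ± 0.14), IER3, NFKB2 (0.64 ± 0.13 and 0.70 ± 0.13) and PLAU (0.46 ± 0.10 and 0.55 ± 0.10). At 3 h NFKB2 and PLAU lost their calls without the siNupr1 3 h array (adjusted p = 0.0606 and 0.0962), and NFKB2 also without the siCtrl 0 h array (0.116). The camera adjusted p of the list was 4.87e-05 and 0.0173, and adjusted p = 0.223 and 0.458 with an estimated correlation. Of 19 aminoacyl-tRNA synthetases 6 and 8 rose and 2 and 1 fell at 3 and 6 h (7 and 8 against 2 and 2 adjusted over the list alone). Camera gave adjusted p of 0.00385 and 0.00283, and with an estimated correlation adjusted p = 0.223 and 0.22. Of 19 p53 targets 6 and 9 rose and 1 and 2 fell (7 and 9 against 1 and 2 adjusted over the list alone). Here camera gave adjusted p of 0.00134 and 0.0104, and with an estimated correlation adjusted p = 0.169 and 0.22. Of 14 hypoxia targets 4 and 6 rose and 2 and 2 fell (6 and 6 against 3 and 4 adjusted over the list alone). The camera adjusted p was 0.0329 and 0.014, and with an estimated correlation adjusted p = 0.266 and 0.22. Of 21 genes of oxidative phosphorylation 5 fell and 0 rose at 6 h, also when adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.516 with an estimated correlation).

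**Figure D2:**
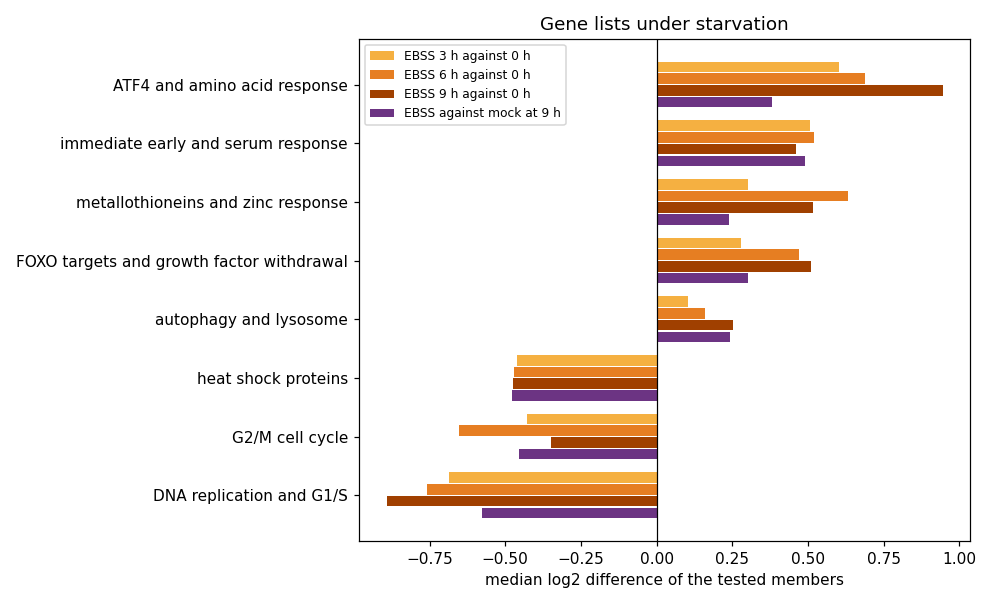
Median log2 difference of the tested members of 8 gene lists (bars) at 3, 6 and 9 h in EBSS against 0 h in the Nupr1 set and in EBSS against mock at 9 h in the NF-kB set. The median of the ATF4 and amino acid response was 0.60, 0.69 and 0.94 at the 3 times and 0.38 against mock, and that of DNA replication and G1/S was -0.69, -0.76, -0.89 and -0.58.

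The NF-kB set compares EBSS with mock at 9 h in siCtrl, siRelA and siRelB cells. Among the genes higher in EBSS were DDIT3 by 1.85 ± 0.16 (n = 3 pairs, adjusted p = 1.53e-08), the transcription factor gene EGR1 by 1.58 ± 0.16, TRIB3 by 1.36 ± 0.13, the cytokine gene LIF by 1.23 ± 0.12 and CHAC1, which degrades glutathione, by 1.23 ± 0.15. EIF5B, a translation initiation factor, fell by 2.34 ± 0.13 (adjusted p = 6.83e-10), THOC2, of mRNA export, fell by 2.22 ± 0.13, and the nuclear pore gene RANBP2 fell by 2.16 ± 0.15. The HSP90 co-chaperone gene CHORDC1 fell by 2.14 ± 0.14 and CLSPN, of the replication checkpoint, fell by 2.05 ± 0.12. In all 2489 genes rose and 3233 fell, 28 and 553 of them at least 2-fold, and 5623 of the called genes moved the same way in all 3 pairs. After quantile normalization 3202 rose and 3069 fell, so that 51.1% of the called genes rose, against 43.5% on the deposited values, and 503 of the 553 were still at least 2-fold lower. Without any 1 of the 6 arrays of the set between 1514 and 1614 rose and between 2551 and 2976 fell. NUPR1 was higher by 0.43 ± 0.12, RELA by 0.42 ± 0.11, RELB by 0.94 ± 0.14 and IER3 by 0.71 ± 0.12. These are means over the 3 pairs, including those in which RELA or RELB was silenced. RELB was at 8.41 in EBSS and 7.11 in mock with siCtrl, and at 6.73 and 6.16 with siRelB. The difference between EBSS and mock fell with the genomic span of the gene (Spearman rho = -0.424 across 11017 genes, which are not independent replicates; -0.448 to -0.357 in the 3 pairs). The genes at least 2-fold lower had a median span of 67.3 kb against 23.3 kb for the other genes. With the span trend removed from each array, 3916 of the called genes were still called, and NUPR1 was not (0.24; adjusted p = 0.0988).

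Of 28 immediate early genes 24 rose and 0 fell in EBSS against mock (25 and 1 adjusted over the list alone; camera adjusted p = 1.75e-07; adjusted p = 0.477 with an estimated correlation), with JUNB at 0.96 ± 0.12. Once the span trend was removed, 16 of them rose and 1 fell, the median went from 0.49 to 0.36, and camera's call was kept. Of the 29 ATF4 genes 19 rose and 3 fell (22 and 3 adjusted over the list alone; camera adjusted p = 0.00012; adjusted p = 0.514 with an estimated correlation). Of 33 autophagy and lysosome genes 16 rose and 4 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.00258; adjusted p = 0.514 with an estimated correlation), with SQSTM1 at 1.20 ± 0.08 and ATG4A at -1.07 ± 0.13. Of 14 heat shock proteins 12 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 3.3e-06; adjusted p = 0.463 with an estimated correlation), with HSPA4L at -1.84 ± 0.13 and HSPH1 at -1.58 ± 0.10. Of 27 DNA replication genes 20 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 5.2e-05; adjusted p = 0.477 with an estimated correlation), with CDC6 at -1.53 ± 0.09. Of 26 G2/M genes 18 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000152; adjusted p = 0.477 with an estimated correlation), with CENPF at -1.63 ± 0.17 and KIF11 at -1.63 ± 0.12. Of 24 ribosome biogenesis genes 16 fell and 3 rose, and of 17 cholesterol genes 9 fell and 1 rose, in both cases also when adjusted over the list alone. NOP58 was at -1.43 ± 0.11 and MSMO1 at -1.56 ± 0.11; the camera adjusted p was 0.00391 and 0.0216, and adjusted p = 0.477 with an estimated correlation for each. Of 17 canonical NF-kB targets 9 rose and 2 fell, also when adjusted over the list alone. NFKB2 was at 1.12 ± 0.11, TNIP1 at 0.63 ± 0.12, EFNA1 at 0.61 ± 0.12, PLAU at 0.59 ± 0.08, CXCL2 at 0.45 ± 0.12, NFKBIE at 0.41 ± 0.11 and BCL3 at 0.34 ± 0.11, beside LIF and IER3, while REL was at -0.92 ± 0.12 and SOD2 at -0.28 ± 0.09. The calls of CXCL2, NFKBIE, BCL3 and SOD2 were lost with the span trend removed (adjusted p from 0.0821 to 0.566) and without single arrays of the siCtrl or siRelA pair (up to 0.214). Camera's adjusted p for the list was 0.018, 0.0666 with the span trend removed, and adjusted p = 0.514 with an estimated correlation. Of 19 ribosomal proteins 7 rose and 1 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0434; adjusted p = 0.608 with an estimated correlation). Of 18 histones 7 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.608 with an estimated correlation). With the span trend removed both turned, to 0 up and 5 down in each list, with medians of -0.10 and -0.15 and no call by camera. Of 18 FOXO targets 9 rose and 3 fell and of 20 ER chaperones 3 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 0.0309 and 0.0419; adjusted p = 0.599 and 0.477 with an estimated correlation).

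**Figure D3:**
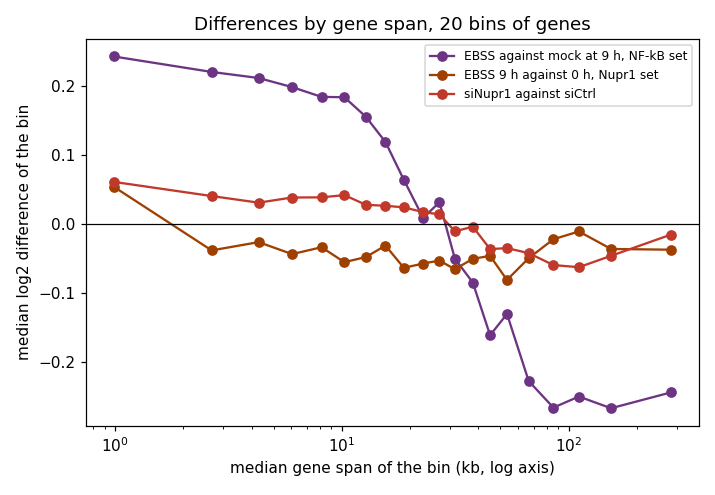
Median log2 difference of 20 bins of genes ordered by genomic span (kb, log axis) for EBSS against mock at 9 h in the NF-kB set, EBSS at 9 h against 0 h in the Nupr1 set, and siNupr1 against siCtrl. Only the NF-kB set's line falls steeply, with a Spearman rho across genes of -0.424 against -0.022 and -0.187.

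The starvation responses of both sets were compared directly, with the reservation that their fed references differ in medium and time. The siRNAs over which each response is a mean differ too: siCtrl, siRelA and siRelB in the NF-kB set, siCtrl and siNupr1 in the other. Of the genes called in both at 9 h, 423 rose and 1020 fell in both, where 229 and 487 would be shared if the calls were independent (Fisher's exact test, p = 1.14e-46 and 4.69e-194), while 33 rose against mock and fell against 0 h and 226 did the reverse. This test counts genes as independent units and the comparisons share each gene's spread, so its p does not measure variation between arrays. The log2 differences correlated at r = 0.387 and rho = 0.391 across genes. Among the shared genes with the largest changes, DDIT3, TRIB3, LIF, EGR1 and SQSTM1 rose in both, and SKP2, ID3, CDC6 and the interleukin receptor gene IL1R1 fell in both. A test of the difference between the responses called 2698 genes, 894 with a more positive and 1804 with a more negative response in the NF-kB set. SLC7A11 was at -0.36 against mock and at 3.39 against 0 h, a difference of -3.74 ± 0.22 (adjusted p = 3.19e-09), and THOC2 differed by -2.38 ± 0.21. ID3 differed by 1.37 ± 0.15, since it fell less against mock (-1.43). Of the 29 ATF4 genes 21 had the more negative response in the NF-kB set and 0 the more positive one. Within that set the median response of this list to EBSS differed from that of siCtrl by -0.45 with siRelA and -0.30 with siRelB. Part of the difference between the sets may therefore come from the siRNAs. Of 27 DNA replication genes 14 had the more positive and 1 the more negative response there.

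Silencing of NUPR1 addresses whether this chromatin protein is needed for the expression of survival genes in starved cells. TNFRSF9, which encodes a costimulatory receptor of the TNF family, was lower with siNupr1 by -1.17 ± 0.10 (n = 4 pairs, adjusted p = 1.3e-06; between -1.34 and -1.01 at the 4 times). The chemokine gene CXCL8 was at -0.95 ± 0.15, the DNA repair gene FANCI at -0.90 ± 0.09, the non-coding RNA UCA1 at -0.86 ± 0.07 and NFKB2, whose product p52 partners RELB, at -0.82 ± 0.09. Among the 10 largest rises were the tubulin gene TUBB4A (1.09 ± 0.11), the matrix protein gene THBS3 (1.09 ± 0.10), MYH16 (0.99 ± 0.09) and the adhesion gene L1CAM (0.95 ± 0.11). SNORD116-24 (1.03 ± 0.15) and SNORD116-14 (0.99 ± 0.18), also among them, belong to a family of near-identical copies, so which copy was measured is uncertain. In all 1087 genes rose and 946 fell, 4 and 1 of them at least 2-fold; 1901 of the called genes moved the same way in all 4 pairs. IER3 differed by -0.21 ± 0.10 and did not pass (adjusted p = 0.16), with -0.44 at 9 h and -0.30, -0.02 and -0.07 at 3, 6 and 0 h. Without the time term, where differences between times count as noise, the calls of TNFRSF9, CXCL8, NFKB2, TUBB4A and both SNORD116 genes were lost (adjusted p from 0.0548 to 0.0928). The count of genes was 1261 with the 3 starved pairs, 3271 with array weights and 113 without the time term, and without either 0 h array or either 3 h array of the set it was 1259, 1262, 840 and 840. The 3 starved pairs gave 608 up and 653 down. Without the siCtrl 6 h array 626 rose and 763 fell, and without the siNupr1 6 h array 624 and 763. The difference fell slightly with gene span (rho = -0.187 across genes; -0.179 to -0.041 in the 4 pairs).

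Of 17 canonical NF-kB targets, 7 fell with siNupr1 and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 2.17e-05; adjusted p = 0.321 with an estimated correlation). Besides CXCL8 and NFKB2 these were the inhibitor gene NFKBIA (-0.76 ± 0.10), LIF (-0.58 ± 0.10), CXCL1 (-0.57 ± 0.12), NFKBIE (-0.43 ± 0.09) and PLAU (-0.27 ± 0.07). The 17 are those that passed the filter on dim genes, of 30 canonical NF-kB targets with a cluster of their own. Of 8 components of the alternative NF-kB pathway 4 fell and 0 rose, also when adjusted over the list alone: NFKB2, the kinase genes MAP3K14 (-0.65 ± 0.09) and CHUK (-0.62 ± 0.10), and BIRC2 (-0.61 ± 0.09). The camera adjusted p was 0.000864, and adjusted p = 0.321 with an estimated correlation. Of 26 G2/M genes 12 fell and 0 rose (19 and 0 adjusted over the list alone; camera adjusted p = 1e-07; adjusted p = 0.321 with an estimated correlation), with DLGAP5 at -0.59 ± 0.11 and CDK1 at -0.52 ± 0.09. Of 28 immediate early genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.000665; adjusted p = 0.519 with an estimated correlation), with EGR1 at -0.62 ± 0.14 (adjusted p of up to 0.0753 without either 3 h array). Of 29 ATF4 genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.000375; adjusted p = 0.519 with an estimated correlation), with PSPH as the gene that rose (0.35 ± 0.08). In the fit without the time term NFKBIA alone of the genes named here kept its call, the others' adjusted p lying between 0.0612 for CXCL8 and 0.608 for EGR1. CXCL1 also lost it without the siCtrl 3 h array (adjusted p = 0.0507).

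Several metabolic lists went the other way. Of 21 genes of oxidative phosphorylation 8 rose with siNupr1 and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.17e-05; adjusted p = 0.321 with an estimated correlation), with NDUFA1 at 0.41 ± 0.07. Of 19 glycolysis genes 8 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000614; adjusted p = 0.321 with an estimated correlation), with PFKL at 0.44 ± 0.08 and PFKM at 0.40 ± 0.08. Of 17 cholesterol genes 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.000614; adjusted p = 0.321 with an estimated correlation), with DHCR7 at 0.42 ± 0.07 and ACAT2 at 0.41 ± 0.08. Of 33 autophagy and lysosome genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.00483; adjusted p = 0.519 with an estimated correlation), with ATG2A at 0.67 ± 0.09 and the lysosomal protease gene CTSB at 0.48 ± 0.07. Of 19 ribosomal proteins 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00366, and 0.0947 with the span trend removed; adjusted p = 0.519 with an estimated correlation). Of 11 anti-apoptotic regulators 4 fell and 0 rose, also when adjusted over the list alone, and camera made no call (adjusted p = 0.0713); besides BIRC2 they were CFLAR (-0.49 ± 0.08), BIRC6 (-0.41 ± 0.09) and MCL1 (-0.31 ± 0.09). In the fit without the time term CTSB kept its call, while NDUFA1, PFKL, PFKM, DHCR7, ACAT2 and ATG2A lost theirs (adjusted p from 0.0627 to 0.272).

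Whether the siNupr1 difference changed with hours of starvation was tested as a slope. With limma 0 genes passed, while 2149 had an unadjusted p under 0.05, and camera called 0 lists. The genes with the smallest p were FIGNL1, FAM111A and ZNF485 with positive slopes and PRKCD, BAG6 and DAXX with negative ones, from 0.16 ± 0.03 per hour for FIGNL1 to -0.13 ± 0.02 for PRKCD (adjusted p = 0.0968 for each). The slopes were -0.01 ± 0.03 for NUPR1, -0.07 ± 0.02 for RELA, -0.07 ± 0.03 for RELB and -0.03 ± 0.03 for IER3 (adjusted p = 0.929, 0.131, 0.267 and 0.61). With the spread taken from the Nupr1 set alone 841 genes were called, RELA among them (adjusted p = 0.0242), while 66 and 46 were called without the siRelA EBSS and mock arrays and 1 without either 0 h array. On simulated data 5.97% of 1.5-fold, 71.6% of 2-fold and 100% of 4-fold changes of this kind were recovered.

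Silencing of RELA was measured in EBSS and in mock. TNFRSF9 was lower with siRelA by -2.12 ± 0.15 (n = 2 pairs, adjusted p = 1.49e-08), RNF141 by -1.81 ± 0.15, the nuclear pore gene NUP58 by -1.81 ± 0.12, the kinetochore gene ITGB3BP by -1.69 ± 0.18 and the cytokine receptor gene IL6ST by -1.62 ± 0.16. The nucleolar protein gene NOLC1 was higher by 2.01 ± 0.11, MICAL2, which oxidizes actin, by 1.64 ± 0.14, ZW10 by 1.44 ± 0.14 and the collagen gene COL6A3 by 1.38 ± 0.12. In all 1116 genes rose and 1255 fell, 36 and 110 of them at least 2-fold. NUPR1 was at -0.29 ± 0.14 and IER3 at -0.17 ± 0.14, and neither passed (adjusted p = 0.174 and 0.45). Without any 1 of the 4 arrays of this comparison between 1120 and 1384 genes were called, with 695 up and 689 down without the siRelA EBSS array and 429 and 691 without the siCtrl mock array. Of 17 canonical NF-kB targets 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.00156; adjusted p = 0.517 with an estimated correlation): CXCL8 (-1.32 ± 0.22), PLAU (-0.73 ± 0.10), LIF (-0.72 ± 0.14), CXCL2 (-0.71 ± 0.15), NFKBIA (-0.62 ± 0.14), TNFAIP2 (-0.51 ± 0.14), NFKB2 (-0.49 ± 0.13) and NFKBIE (-0.47 ± 0.13). Of these, CXCL2, NFKBIA, TNFAIP2, NFKB2 and NFKBIE lost their calls without the siCtrl EBSS or the siRelA EBSS array, with adjusted p of up to 0.227. Of 26 G2/M genes 12 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 1.03e-05; adjusted p = 0.517 with an estimated correlation), with CDK1 at -1.58 ± 0.12 and TTK at -1.29 ± 0.18. Of 18 histones 11 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 1.03e-05; adjusted p = 0.517 with an estimated correlation), with H4C2 at -0.67 ± 0.13 (adjusted p = 0.0957 without the siRelA mock array). Histone genes too are near-identical, so single members are uncertain. Of 29 ATF4 genes 11 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 0.000398; adjusted p = 0.532 with an estimated correlation), with DDIT4, an inhibitor of mTORC1, at -1.19 ± 0.18. Of 19 p53 targets 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00646; adjusted p = 0.517 with an estimated correlation), with the death receptor gene FAS at -0.92 ± 0.14. Of 9 metallothionein genes 3 rose and 0 fell, also when adjusted over the list alone, and of 6 epithelial markers 2 rose and 0 fell (4 and 0 adjusted over the list alone); the camera adjusted p was 0.0279 and with an estimated correlation adjusted p = 0.517 for each.

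Silencing of RELB was measured in the same media. RAB21 was lower with siRelB by -2.11 ± 0.13 (n = 2 pairs, adjusted p = 2.29e-09) and RAP1B by -1.91 ± 0.11, both small GTPase genes, and YAE1 was at -1.76 ± 0.14, NUF2, of the kinetochore, at -1.59 ± 0.16 and ECT2, of cytokinesis, at -1.58 ± 0.13. GANAB, which trims glycoproteins in the ER, was higher by 1.60 ± 0.10, NOLC1 by 1.52 ± 0.11, OGFR by 1.34 ± 0.11 and ZDHHC16 by 1.28 ± 0.11. In all 836 genes rose and 943 fell, 22 and 63 of them at least 2-fold, and without any 1 of the 4 arrays of this comparison between 761 and 847 were called. IER3 was lower by -0.50 ± 0.14 (adjusted p = 0.0209), with -0.78 in EBSS and -0.21 in mock. Its call was lost in the fits without the siCtrl EBSS or the siRelB EBSS array of the set (adjusted p of up to 0.423, with a difference of -0.28). Of 17 canonical NF-kB targets 7 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.762 with an estimated correlation): CXCL8 (-0.97 ± 0.22), IER3, PLAU (-0.48 ± 0.10), NFKBIA (-0.45 ± 0.14), LIF (-0.45 ± 0.14), CXCL2 (-0.44 ± 0.15) and NFKB2 (-0.43 ± 0.13). Each of these 7 lost its call without at least 1 of the siCtrl EBSS, siRelB EBSS and siRelB mock arrays, with adjusted p of up to 0.0830 for PLAU and 0.617 for CXCL2. CXCL8 also lost it with robust eBayes (adjusted p = 0.0874), and NFKBIA, LIF and CXCL2 without the filter on dim genes (0.0574 for LIF, 0.0814 for CXCL2). Of 26 G2/M genes 15 fell and 0 rose (17 and 0 adjusted over the list alone; camera adjusted p = 1.07e-12; adjusted p = 0.707 with an estimated correlation), with TTK at -1.51 ± 0.18, HMMR at -1.45 ± 0.18 and CDK1 at -1.11 ± 0.12. Of 14 heat shock proteins 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00786; adjusted p = 0.762 with an estimated correlation), with CHORDC1 at -1.36 ± 0.17. Of 29 ATF4 genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00786; adjusted p = 0.914 with an estimated correlation), with PSAT1 at -0.84 ± 0.12. Of 11 anti-apoptotic regulators 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.799 with an estimated correlation): BIRC2 was at -1.40 ± 0.13, CFLAR at -0.45 ± 0.12 and BCL2L1 at 0.44 ± 0.12, beside IER3. CFLAR and BCL2L1 lost their calls without the siRelB mock array, among others (adjusted p of up to 0.162 and 0.429). Of 18 histones 1 fell and 0 rose (0 adjusted over the list alone; camera adjusted p = 0.00786; adjusted p = 0.944 with an estimated correlation), and of 8 alternative NF-kB components 5 fell and 0 rose without a call by camera (5 and 1 adjusted over the list alone; camera adjusted p = 0.0526).

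**Figure D4:**
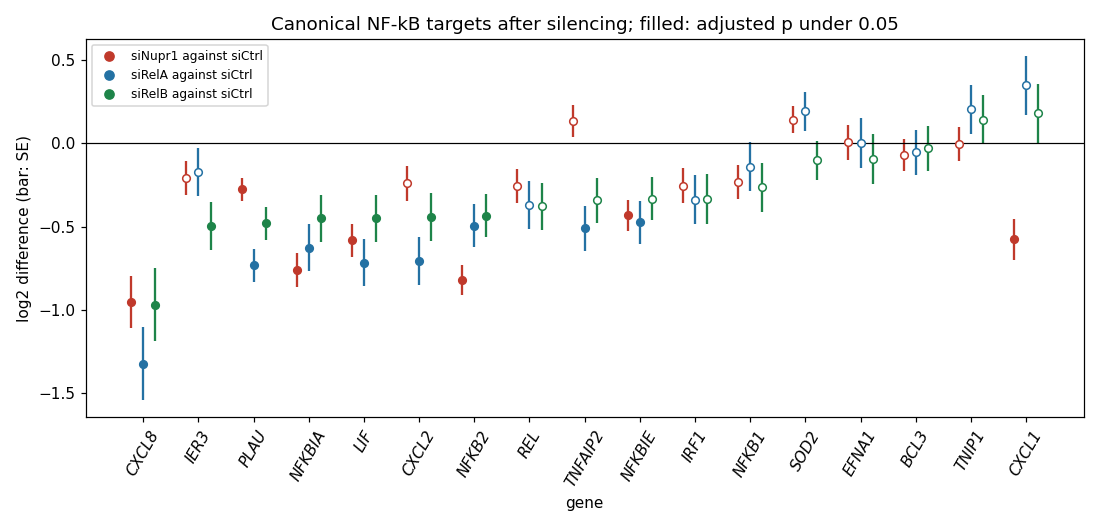
Log2 difference (points; bars are SE) of the 17 tested canonical NF-kB targets with siNupr1, siRelA and siRelB against siCtrl; filled points passed the threshold. CXCL8 was at -0.95, -1.32 and -0.97, IER3 passed with siRelB only, and no target passed upward.

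The direct contrast of siRelB with siRelA compares the cells treated with these siRNAs. Silencing was unequal: against siCtrl, RELA was at -2.63 in EBSS and -2.36 in mock with siRelA. RELB was at -1.68 and -0.95 with siRelB. A called gene therefore need not depend on one NF-kB subunit more than on the other. The contrast called 602 genes as higher and 508 as lower with siRelB, 38 and 22 of them at least 2-fold. RELA was higher by 2.51 ± 0.13 and RELB lower by -0.95 ± 0.17 (n = 2 pairs, adjusted p = 5.25e-10 and 0.00125; the latter up to 0.0831 with 1 array left out). NUP58 was higher by 1.46 ± 0.12 and ACBD5 by 1.43 ± 0.14 with siRelB, and DDAH1, which breaks down methylated arginine, was lower by -1.94 ± 0.13, RAB21 by -1.61 ± 0.13 and the citrate cycle gene IDH3A by -1.52 ± 0.13. The difference for IER3 was -0.32 ± 0.14 and did not pass (adjusted p = 0.168), nor did that for NUPR1 (-0.15 ± 0.14, adjusted p = 0.623). Of 17 canonical NF-kB targets 0 differed by limma, also when adjusted over the list alone. Of 28 immediate early genes 4 were lower and 0 higher with siRelB (8 and 1 adjusted over the list alone; camera adjusted p = 0.00139; adjusted p = 0.763 with an estimated correlation), with CCN1 at -1.16 ± 0.20 (adjusted p = 0.072 without the siRelA mock array). Of 6 epithelial markers 2 were lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.686 with an estimated correlation), and of 18 histones 2 were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.0283; adjusted p = 0.763 with an estimated correlation). With the span trend removed 1 histone was higher, the median went from 0.21 to 0.10 and camera made no call (adjusted p = 0.299). Of 33 autophagy and lysosome genes 3 were lower and 2 higher (4 and 2 adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.763 with an estimated correlation). Without any 1 of the 4 siRelA and siRelB arrays 646, 357, 442 and 313 genes were called. The balance turned to 287 higher and 359 lower without the siRelA EBSS array and to 153 and 160 without the siRelB mock array.

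Whether an siRNA's difference was larger or smaller in EBSS than in mock was tested directly; a gene that depends on RelB in both media would not be called. For siRelB limma called 0 genes by this test, while 401 had an unadjusted p under 0.05, and IER3 differed by -0.57 ± 0.27 and RELB by -0.73 ± 0.32 (adjusted p = 1.0 for each). The genes with the smallest p were ID2 (1.43 ± 0.28), MIGA1, ZNF12 (-1.21 ± 0.26) and SLU7, none of which passed (adjusted p = 0.703 for ID2 and 0.726 for ZNF12). For siRelA limma called 4 genes, 3 small nucleolar RNA genes and the pseudogene SNORD13P3, with a more positive siRelA difference in EBSS than in mock: SNORD13P3 (2.01 ± 0.26), SNORD13 (1.59 ± 0.25), SNORD33 (1.23 ± 0.13) and SNORD57 (1.19 ± 0.19). SNORD13 and SNORD13P3 are near-identical, so their signals cannot be assigned to one of them. Among the 29 ATF4 genes 0 passed over all genes, while adjusted over the list alone 7 had a more negative siRelA difference in EBSS than in mock (camera adjusted p = 4.86e-13; adjusted p = 0.424 with an estimated correlation). SESN2 was at -1.55 ± 0.29, CTH at -1.30 ± 0.26, ATF3 at -1.29 ± 0.30 and CHAC1 at -1.24 ± 0.27. For siRelB 2 of these 29 did so adjusted over the list alone (camera adjusted p = 7.28e-09; adjusted p = 0.57 with an estimated correlation), with ATF3 at -1.20 ± 0.30. The siRelA and siRelB tests share the siCtrl EBSS and mock arrays. Likeness between them, in this list or others, may therefore come from those arrays. In the other lists that camera called 0 members passed over all genes. For siRelA the difference was the more negative in EBSS for canonical NF-kB targets (median -0.32, camera adjusted p = 0.00331), FOXO targets (-0.29, 0.00391), immediate early genes (-0.34, 0.0022), anti-apoptotic regulators (-0.47, 0.0022) and aminoacyl-tRNA synthetases (-0.18, 0.0184). It was the more positive for cholesterol genes (0.17, 0.0142), histones (0.24, 5.93e-06) and the 4 fibroblast markers (0.43, 0.025). With the span trend removed the histone median was 0.09 (camera adjusted p = 0.0365). With an estimated correlation adjusted p lay between 0.424 and 0.591 for these 8 lists. For siRelB it was the more negative for anti-apoptotic regulators (-0.32, 0.00897), oxidative phosphorylation (-0.18, 0.00166) and histones (-0.20, 9.27e-05), with adjusted p = 0.57, 0.638 and 0.736 with an estimated correlation. Adjusted over the list alone 1 synthetase passed for siRelA and 2 histones for siRelB. On simulated data 53.7% and 46.3% of 2-fold differences of this kind were recovered for siRelA and siRelB, and the counts were 39 and 6 with array weights. The siRelA count was 0 without an intensity trend in the variance, 1 without small non-coding RNA genes, 2 with the span trend removed, and between 11 and 25 without any 1 of the 8 arrays of the Nupr1 set, from which the spread is taken.

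The differences of the 3 siRNAs overlapped. With siNupr1 and siRelB, whose comparisons share no array, 266 genes rose and 304 fell in both, where 82.4 and 80.9 would be shared if the calls were independent (Fisher's exact test, p = 6.46e-77 and 1.08e-108), while 20 rose with siNupr1 and fell with siRelB and 19 did the reverse. This test counts genes as independent units, and the comparisons share each gene's estimate of the spread. Its p therefore does not measure variation between arrays, and calls may coincide more often than independence implies. The largest changes among the genes lowered by both included CXCL8, TNFRSF9, the mitotic gene NUF2, the tight junction gene CLDN1 and UCA1, and among those raised GANAB, MYH16, the annexin gene ANXA6 and ZDHHC16. With siNupr1 and siRelA, which share no array either, 303 rose and 383 fell in both, against 110 and 108 if independent, while 54 rose with siNupr1 and fell with siRelA and 20 did the reverse. The log2 differences correlated across genes at r = 0.427 (rho = 0.386) for siNupr1 with siRelB and r = 0.412 (rho = 0.368) with siRelA. With siRelA and siRelB, which share their siCtrl arrays, 496 rose and 517 fell in both and r was 0.66, while unchanged groups simulated on shared controls gave r between 0.48 and 0.516, a covariance of 0.00913 against 0.0665, and at most 1 shared call. NOLC1, GANAB, MICAL2, NUF2, TTK and CDK1 were among the genes changed alike by both. The simulated noise was independent between genes and arrays. A deviation of the shared siCtrl arrays that runs across many genes could still produce such likeness, and the simulation does not exclude it.

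Markers of other cell types were mostly too dim to be tested. Of the fibroblast, leukocyte, acinar and endothelial markers with a cluster of their own, 4 of 11, 2 of 10, 1 of 4 and 0 of 6 were tested, against 6 of 9 epithelial and ductal markers. All 6 epithelial markers rose in EBSS against mock, also when adjusted over the list alone (camera adjusted p = 0.00865; adjusted p = 0.477 with an estimated correlation), with KRT19 at 0.49 ± 0.08; with the span trend removed 3 rose. In the Nupr1 set 0 of the 6 passed at 3 and 9 h, also when adjusted over the list alone, and 1 rose at 6 h (3 adjusted over the list alone; camera adjusted p = 0.0492, and 0.0892 with the span trend removed; adjusted p = 0.356 with an estimated correlation). KRT19 was higher with siNupr1 (0.61 ± 0.07). COL1A2, of fibroblasts, was at -0.91 ± 0.13 in EBSS against mock and at -0.96 ± 0.15 after 9 h in the Nupr1 set, ACTA2 was at 0.51 ± 0.10 against mock, and COL1A1 and COL3A1 did not pass in either. Among the leukocyte markers CD68, a lysosomal protein gene that other cells express too, was at 0.56 ± 0.09 against mock and at 0.55 ± 0.08 with siNupr1, and CD14 did not pass. The acinar marker CELA3A did not pass in any of the starvation or silencing comparisons.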

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

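The tests of a response to any siRNA, of lower RELB, of the fed reference, of compressed signal, of starvation as such, of gene span as the whole cause and of small RNA recovery were chosen after the result was seen, as was the limit to splits that part every pair, while the tests of gene span bias, of the host genes and of other splits of the arrays were set before.

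Some results were singled out by rule. The siRelA difference changed with the medium for 4 genes, which stood out because a difference between groups was itself tested and passed. The starvation response differed between the sets for 2698 genes (894 up and 1804 down), which stood out for the same reason. In EBSS against mock 1110 of 2779 clusters without a single symbol were called (690 up and 420 down), which stood out because they lie outside the comparisons; 438 of 1036 had several symbols and 672 of 1743 were unlisted.

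Genes changed alike with all 3 siRNAs, 180 upward and 202 downward, may reflect any silencing siRNA, or the control siRNA, rather than the protein silenced. Over the 2033 genes called with siNupr1, the siRelA difference signed by the siNupr1 direction had a median of 0.205, with 0.219 in EBSS and 0.184 in mock, but a median above 0 restates the shared changes, so this test leaves it open. If lower RELB after NUPR1 silencing carried the likeness, siRelB should follow siNupr1 more closely than siRelA does, and the signed median of siRelB minus siRelA was -0.017, with -0.053 in EBSS and 0.024 in mock, so that test leaves the question open. Of the 1110 genes called between siRelB and siRelA, 46.8% had a siNupr1 difference of the same sign. Across them r was -0.056, and -0.033 across all genes. That contrast also holds the siRelA differences, so these values do not decide it either. A second control siRNA and a second siRNA for each gene would separate the explanations.

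More genes fell at least 2-fold in EBSS in the NF-kB set, where 553 were so called, against 100 in the Nupr1 set at 9 h. After quantile normalization 503 remained. The quartiles of the arrays were already close before that step (for siCtrl 4.199 and 7.436 in EBSS, 4.156 and 7.464 in mock). It could therefore hardly remove falls of 2-fold, and whether compressed signal plays a part stays open. The fed reference, which differs between the sets, stays open too. The gap between sets was larger on the EBSS than on the fed arrays in 100% of 6 array pairs. The choice of genes that fell fixes this outcome. Gene span may account for a part. After the trend on span was taken from the difference around its median, 261 remained at least 2-fold lower. When each array kept its own mean level, 359 remained and all 553 were still called. Counts among genes chosen at that cut can only fall. Over all genes 397 were called at least 2-fold lower when each array kept its own mean level. In the latter case the median of the 553 went from -1.22 to -1.099 and the SD of their differences from 0.243 to 0.273. These genes were chosen for a fall of at least 2-fold, while the medians of the span bins lay between 0.2435 and -0.2673. Removing a trend of that size could not take away such falls, so it cannot tell whether span is the whole cause. Whether starvation as such lowered long genes stays open, since in the Nupr1 set rho with gene span was -0.022 at 9 h, but -0.199 at 3 h (-0.186 and -0.164 in the pairs) and -0.128 at 6 h (-0.158 and -0.054).

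Of 86 small nucleolar RNA genes 35 rose with siNupr1 and 0 fell, 25 fell with siRelA and 0 rose, 4 rose with siRelB and 0 fell, and 41 were higher and 0 lower with siRelB against siRelA, with medians of 0.30, -0.32, 0.20 and 0.45. If recovery of small RNA differed between arrays, the 15 small nuclear RNA genes should have shifted likewise, and they did so in 1 of these 4 comparisons, siNupr1 (0.36, 0.04, 0.01 and -0.01). If the host genes had changed, the 35 hosts of 47 of these genes should have shifted, and they did so in 1 of 4, siRelA (-0.01, -0.12, -0.06 and 0.06). A common cause of all 4 shifts was not found with these values. The siNupr1 comparison shares no array with the others, and for it a difference in small RNA recovery stays open. For siRelA a change of the host genes stays open.

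Other splits of the arrays were counted for both main comparisons. The arrays are paired by time or by siRNA, so the real split was set beside those that part every pair, although the test set before counted all splits. For siNupr1 the real split gave 2033 genes and the highest of the other 7 gave 0, but 8 splits are too few to decide; 24 splits that part 2 of the 4 pairs gave at most 862, reached where the 0 h and 3 h pairs were parted as in the real split, and 3 that part none could not be fitted. For EBSS against mock the real split gave 5722 genes and the highest of the other 3 gave 0, but 4 splits are too few to decide, and 6 that part fewer pairs gave at most 0.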

How the results depend on the processing

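Many of the fits that left out an array dropped an array outside the comparison's own pairs. Those could change a label only through the estimate of the spread. The 670 gene results kept their label in 6499 of 6656 values from other settings and in 8719 of 9092 values from fits that left out an array. Of the rest, 117 and 287 were weaker, 34 and 68 stronger, and 3 and 0 reversed. The reversed ones, all with the span trend removed, were RPL10A, EBSS against mock at 9 h, at -0.015, RPL7A, EBSS against mock at 9 h, at -0.0132, and H4C1, EBSS against mock at 9 h, at -0.057, none of them called there; the trend's removal lowers short genes by construction. Dim genes limit the arrays. The filter left out genes with a low mean over all arrays, so a kept gene can lie below its level of 5.805 on single arrays. NUPR1 did so, at 5.59 with siNupr1 at 0 h.

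With array weights the counts of genes were 2173 at 3 h, 1517 at 9 h, 3271 for siNupr1, 39 for siRelA by medium and 6 for siRelB by medium; the cause was not tested. For siNupr1 the 3 starved pairs gave 1261, with fewer arrays, and the fit without the time term gave 113. That fit used the arrays of the Nupr1 set alone and gave up the pairing by time, so that differences between times counted as noise. For siNupr1 by hours the spread of the own set gave 841 genes, 257 up and 584 down. For siRelA by medium eBayes without trend gave 0, leaving out small non-coding RNA genes 1 and removing the span trend 2. With an estimated correlation 0 lists were called in each of the comparisons, that is EBSS against mock, 3 h, 6 h, 9 h, siNupr1, siRelA, siRelB, siRelB against siRelA, siRelA by medium and siRelB by medium. With fry 1 list was called for siRelB and 0 for siRelB against siRelA, siRelA by medium and siRelB by medium. At an unadjusted p under 0.05 the number of genes lowered by both siNupr1 and siRelB was 665 and that of genes changed by both siRelA and siRelB was 1820, as more genes enter.

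Leaving out each array in turn, the number of genes called lay between 4065 and 6253 for EBSS against mock, 356 and 1710 at 3 h, 823 and 2990 at 6 h, and 1639 and 2703 at 9 h. It lay between 840 and 2403 for siNupr1, 1120 and 2720 for siRelA, 761 and 2151 for siRelB, and 313 and 1442 for siRelB against siRelA. For siNupr1 by hours it lay between 0 and 66, for siRelA by medium between 4 and 25, and for siRelB by medium it was 0 throughout; for the last pair 10 of the 14 arrays could be left out.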

Other observations

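The genes of the ID proteins, which hold back helix-loop-helix transcription factors and are known targets of BMP and serum signalling, were looked at after their values were seen. ID3 was at -1.74, -2.35 and -2.80 after 3, 6 and 9 h in EBSS, ID2 at -2.47, -3.02 and -2.52, and ID1 at -1.32, -0.73 and -0.69, all past the threshold. Against mock at 9 h ID1 was at -1.08, ID2 at -1.26 and ID3 at -1.43, also past it. With siNupr1 none of the 3 passed. With siRelA ID3 was at 0.64 (adjusted p = 0.000547), and with siRelB against siRelA it was at -0.60 (adjusted p = 0.00206).

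By gene type, 35 of 86 small nucleolar RNA genes and 11 of 15 small nuclear RNA genes rose with siNupr1 and 0 fell, while of 36 microRNA genes 0 changed in either direction. Against mock 60 of 179 long non-coding RNA genes rose in EBSS and 9 fell. These types were counted after the data were seen, and no test of the types as groups was made.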
